A study of Mus musculus with 17 samples.

How the data were processed

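Gene expression was measured in tibialis anterior muscle of male mice aged 8 weeks on 17 single-colour bead arrays, 1 array per sample, with muscles taken at day 3. Per the labels' protocols, RNA was extracted with TRIzol and purified on columns with DNase treatment, amplified, and labelled with biotin as cRNA. The labels name 5 groups. Mobile hindlimbs of littermate controls, immobile hindlimbs of littermate controls and immobile hindlimbs of p53 mKO mice have 3 arrays each, and muscles transfected with a control plasmid or with a p53 plasmid have 4 arrays each. The labels do not say which limbs came from the same mouse, so each array was treated as 1 sample. Each p-value weighs a difference of group means against the spread between arrays, which may not be a spread between independent animals.

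The values deposited by the authors are on a log scale, taken here as log2 because they run from 8.21 to 15.61, the range of a scanner on that scale. The authors had normalized the arrays against one another before depositing the log2 values, as seen from near-identical distributions, with array medians from 8.48 to 8.5. The method, the background correction and the log base are not stated per the labels. A floor near the lowest value compresses the differences of dim genes, so that their fold changes are understated. No detection values or bead counts were used here, and the number of arrays limits the precision.

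The table held 25697 probes, each with a value on all 17 arrays. A probe table paired 23978 probes with 1 gene symbol and 0 probes with several, and it left 1719 probes unnamed. Symbols were updated through their gene identifiers, and 99.9% of them matched the reference gene table. Each of the 16593 named genes was represented by the probe with the highest mean over the 17 arrays, 4777 of these genes having several probes. A gene was tested when its value lay above the 40th percentile of the array in at least as many arrays as the smallest group of the fit holds. This left 10842 genes in the immobilization experiment and 10398 in the transfection experiment. No probe was paired with Trp53, the gene that encodes p53, so the knockout and the plasmid were not checked at the gene they target. Myh3, which the rule below also names, likewise had no listed probe.

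Differences were tested with lmFit and eBayes of limma 3.58.1 in R 4.3.3, in 1 fit of the 9 immobilization arrays and 1 fit of the 8 transfection arrays. The p-values were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05, and genes past it are called risen or fallen. Errors after a log2 difference are standard errors (SE) from this fit, and errors after a group mean are standard deviations (SD). The comparisons were immobile against mobile control limbs, immobile p53 mKO against immobile control limbs, immobile p53 mKO against mobile control limbs, and p53 plasmid against control plasmid.

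Before the data were examined, the comparisons, tests, alternatives, rule for named genes and 31 gene lists with 700 entries were fixed. Of the 673 distinct genes in the lists, 601 had a probe. The lists cover p53 targets, ATF4 targets, atrophy with ubiquitin ligases and autophagy, the proteasome, denervation, embryonic and regenerating fibres, slow fibres, fast fibres, mitochondrial respiration, fatty acid oxidation, glycolysis, polyamines, extracellular matrix with fibroblasts, tendon, macrophages, neutrophils, lymphocytes, the interferon response, endothelium, smooth muscle with pericytes, adipocytes, Schwann cells, erythroid cells, proliferation, heat shock, the Nfe2l2 response, the clock, immediate early genes, the glucocorticoid response, ribosomal proteins, and insulin, IGF and myostatin signalling. Each list with at least 5 tested genes was compared with all other genes by camera with a preset correlation of 0.01, adjusted over the lists of a comparison, then again with an estimated correlation and with fry, which tests the members' common direction without other genes. Counts of list members are given over all genes tested and adjusted over the list alone. All list calls made with the preset correlation were lost with the estimated one in every comparison.

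The rule for named genes took, for each comparison, the 12 largest rises and 8 largest falls among called genes whose groups do not overlap, up to 4 members of each list with the smallest p, up to 10 genes called in 2 of the comparisons, and a fixed set of p53, atrophy and denervation genes. For the loss of p53, where nothing passed, it took the 5 leading rises and 5 leading falls by unadjusted p. The genes printed are a selection from that set made after their values were seen, so counts of kept and lost calls are given over the whole set. Fold changes of the 2 experiments were compared by Pearson and Spearman correlation across genes, with an exact permutation of the 8 transfection array labels over 70 assignments. Where comparisons share arrays, values simulated with no effect stand beside the observed ones, once with independent arrays and genes (50 simulations) and once with random weightings of each group's residual arrays, the same for same-numbered immobile arrays (1000 simulations).

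Whether replicate numbers pair the arrays was checked by correlating, across genes, the deviations of same-numbered arrays from their group means. Immobile control and immobile p53 mKO arrays of the same number correlated at 0.621, 0.484 and 0.813, so that their numbers were taken to pair them, a pairing that comes from the data alone and that the labels do not state. No other pair of groups had every correlation above 0.1.

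The alternatives were quantile normalization, centring, no filter, a filter at the 60th percentile, all probes, all 17 arrays in 1 fit, only the groups compared, a variance trend with robust moderation, array weights, a replicate block, an adjusted p under 0.1, and leaving out each array in turn. After the data were seen, 2 alternatives were added, the omission of both immobile arrays numbered 3 and a covariate for macrophage markers. The fits were tested on simulated data with 100 genes changed by a log2 difference of 0.5 and 100 by 1. The fit recovered 84 and 90 of these for immobilization, 70 and 93 for the loss of p53, 78 and 93 for p53 mKO against mobile limbs, and 90 and 100 for transfection. In the same order, 6, 15, 8 and 13 unchanged genes were called. The noise was independent between genes and arrays, with 1 spread per gene for all groups. Correlated genes and the shared deviations of same-numbered arrays were left out, so recovery in the real data may differ. Unnamed probes were left out of the counts of genes.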

Results

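The series asks what p53 does in skeletal muscle that wastes when a limb is immobilized. The tibialis anterior, a muscle of the shin, was measured 3 days after immobilization in mobile control limbs, immobile control limbs and immobile limbs of p53 mKO mice, a strain name that the labels do not spell out (3 arrays each). In a separate experiment the muscle was measured 3 days after transfection with a control plasmid or a p53 plasmid (4 arrays each). Array medians lay between 8.48 and 8.5 on the log2 scale. Trp53 itself had no listed probe, so neither the knockout nor the plasmid could be checked at that gene.

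Immobile control limbs were compared with mobile control limbs to find which genes respond to immobilization. Some genes of protein breakdown and of denervated muscle were higher in immobile limbs, and some genes of energy metabolism were lower. Gadd45a, a growth arrest and DNA damage gene, was 5.75-fold higher, at 13.52 ± 0.54 against 10.99 ± 0.18 (SD, n = 3). Fbxo32 and Trim63, the ubiquitin ligases of muscle atrophy, were 3.74-fold and 2.84-fold higher, and Chrna1, a subunit of the acetylcholine receptor, was 3.42-fold higher on the brightest of its 3 probes. Perm1, a regulator of oxidative metabolism in muscle, had the largest fall (log2 difference -2.32 ± 0.13 SE). Smox, a polyamine enzyme, was 4.75-fold lower, at 10.59 ± 0.15 against 12.84 ± 0.45 (SD, n = 3). Of 10842 genes tested, 553 rose and 690 fell, and 51 of the risen and 48 of the fallen changed at least 2-fold.

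The other large rises were in Hdac4, a deacetylase of denervated muscle (log2 difference 2.28 ± 0.34 SE, adjusted p = 0.00491), Serpina3n (2.10 ± 0.18), Tmem100 (1.91 ± 0.19), the chemokine Ccl8 (1.77 ± 0.21), the glycine transporter Slc6a9 (1.57 ± 0.17) and the cell cycle inhibitor Cdkn1a (1.52 ± 0.17, adjusted p = 0.00156). Large falls after Perm1 were in Smox (-2.25 ± 0.23), the potassium channel genes Kcnc1 (-2.24 ± 0.08) and Kcna7 (-1.62 ± 0.07), the transferrin receptor Tfrc (-1.87 ± 0.23) and Mlf1 (-1.67 ± 0.11). Wfdc17 (1.93 ± 0.47), Junb (1.91 ± 0.42), Srxn1 (1.63 ± 0.38), Mettl21c (-2.09 ± 0.48) and the slow myosin light chain Myl2 (-1.71 ± 0.34) also passed the test. These 5 lost their calls when single arrays were left out, with highest adjusted p of 0.118, 0.0914, 0.105, 0.0964 and 0.0714. Those values came without mobile control array 2 for Wfdc17, Junb and Myl2, array 3 for Srxn1 and array 1 for Mettl21c. Each value is that of 1 probe, and other probes of a gene can differ. The log2 difference ran over the probes from 0.20 to 1.77 for Chrna1 and from -2.24 to -0.21 for Kcnc1, all called, and Fbxo32 (1.48 to 1.90) and Srxn1 (0.70 to 1.63) were called on 2 of 3.

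**Figure D1:**
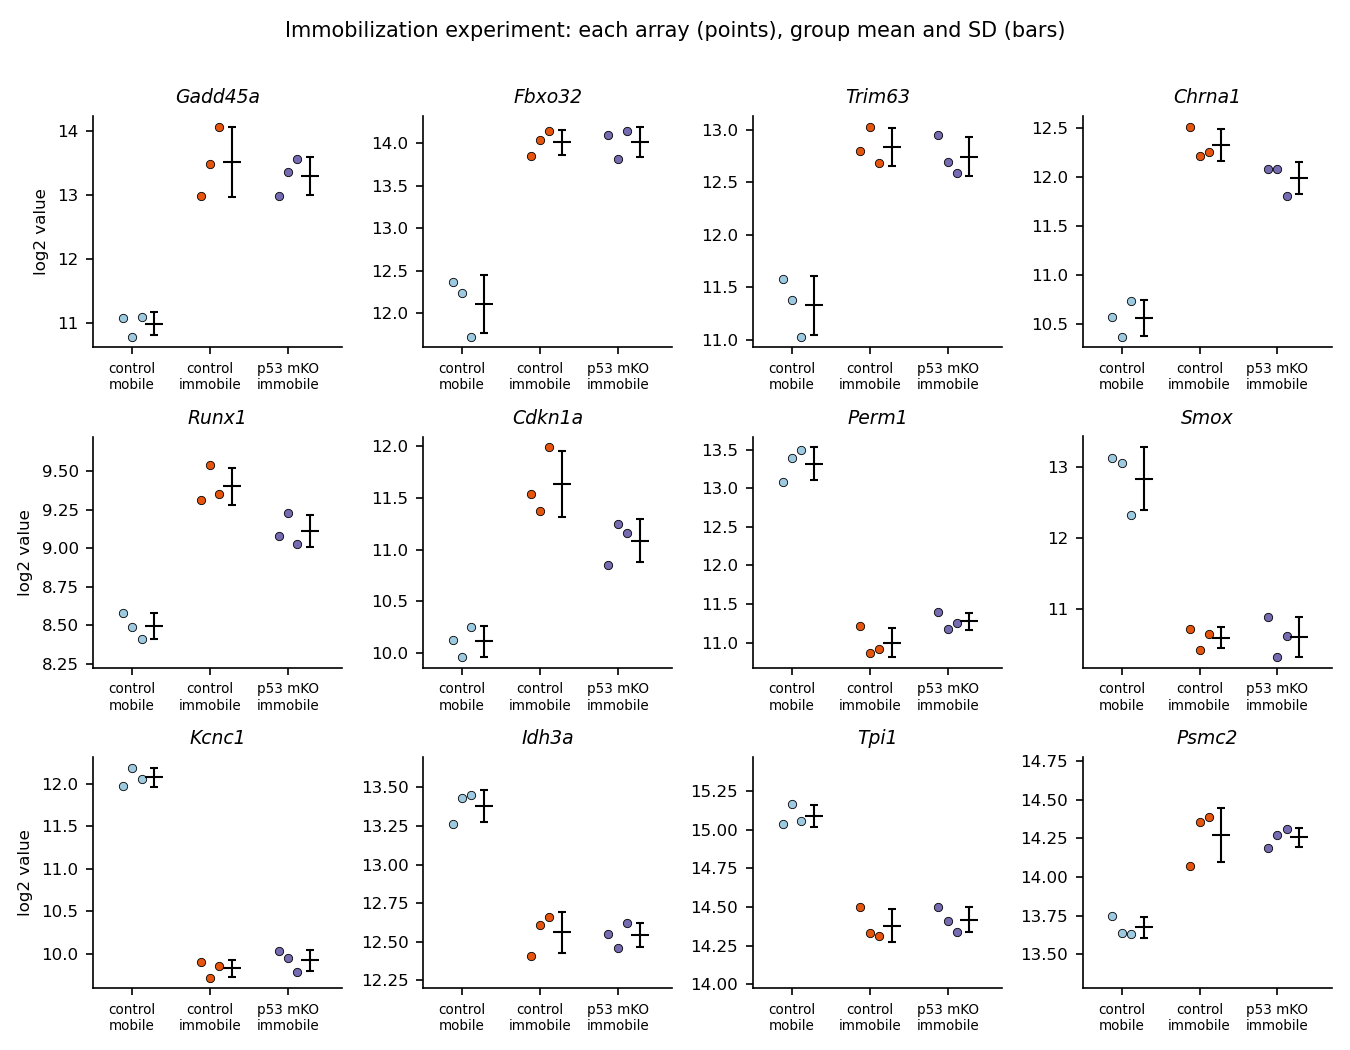
Log2 values of 12 genes on each of the 9 immobilization arrays (points), with group means and SD (bars) in mobile control, immobile control and immobile p53 mKO limbs. Gadd45a lies at 13.52 ± 0.54 in immobile and 10.99 ± 0.18 in mobile control limbs, and Smox at 10.59 ± 0.15 and 12.84 ± 0.45.

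Of 28 proteasome genes tested, 15 rose and 0 fell (20 and 0 adjusted over the list alone), among them Psma5 (0.80 ± 0.09) and Psmc2 (0.60 ± 0.09). The list stood above other genes with an adjusted p = 3.49e-10 by camera and an adjusted p = 0.226 with an estimated correlation. Of 25 genes of atrophy, ubiquitin ligases and autophagy, 7 rose and 0 fell (7 and 0 adjusted over the list alone). By camera this gave an adjusted p = 1.70e-05, and an adjusted p = 0.268 with an estimated correlation. Of 17 denervation genes, 8 rose and 1 fell (10 and 2 adjusted over the list alone), among them Runx1, a transcription factor of denervated muscle (0.91 ± 0.08), and Myog, myogenin (1.13 ± 0.23). Its adjusted p = 3.55e-05 by camera, and adjusted p = 0.0615 with an estimated correlation. Myog was called on 1 of 2 probes (0.11 to 1.13) and lost its call without mobile control array 2 (adjusted p = 0.0666). Of 10 genes of embryonic and regenerating fibres, 2 rose and 0 fell (5 and 1 adjusted over the list alone), Myf6 among the risen (0.77 ± 0.07). Camera gave these an adjusted p = 0.0119, and an adjusted p = 0.227 with an estimated correlation.

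Of 39 genes of mitochondrial respiration, 0 rose and 17 fell (0 and 21 adjusted over the list alone), including the dehydrogenase subunits Idh3a (-0.82 ± 0.08) and Sdhc (-0.64 ± 0.06), and Esrra, a nuclear receptor that drives mitochondrial genes (-0.81 ± 0.08). Sdhc was called on 1 of 2 probes (-0.64 to -0.11). The list had an adjusted p = 7.99e-12 by camera and an adjusted p = 0.0615 with an estimated correlation. Of 16 glycolysis genes, 0 rose and 11 fell (0 and 11 adjusted over the list alone), including triosephosphate isomerase Tpi1 (-0.71 ± 0.07) and muscle glycogen synthase Gys1 (-1.06 ± 0.13), Tpi1 on 2 of 3 probes (-1.02 to -0.48). As a list they had an adjusted p = 1.71e-07 by camera and an adjusted p = 0.0615 with an estimated correlation. Of 22 genes of fatty acid oxidation, 1 rose and 6 fell (1 and 10 adjusted over the list alone), including the carnitine transferase Cpt1b (-0.49 ± 0.05) and the fatty acid binding protein Fabp3 (-0.60 ± 0.08). Together they reached an adjusted p = 0.000148 by camera and an adjusted p = 0.226 with an estimated correlation. The risen member was Angptl4, an inhibitor of lipoprotein lipase (1.07 ± 0.28), whose call was lost without mobile control array 2 (adjusted p = 0.156). Of 17 fast fibre genes, 0 rose and 3 fell (0 and 3 adjusted over the list alone). The list had an adjusted p = 0.0131 by camera and an adjusted p = 0.377 with an estimated correlation. That call was also lost without mobile control array 2 (0.0533) or immobile control array 2 (0.0951) and with quantile normalization (0.0552). Of 14 slow fibre genes, 0 rose and 2 fell (0 and 3 adjusted over the list alone), among them Myoz2 (-0.78 ± 0.05), and the list did not pass (lower, adjusted p = 0.0549). It was called lower with fry (0.0135), with no filter (0.0339), without mobile control array 2 (0.0101) and without immobile control array 1 (0.0110).

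Of 34 p53 targets, 5 rose and 3 fell (5 and 4 adjusted over the list alone), and the list did not pass (higher, adjusted p = 0.0591 by camera). It was called higher with fry (0.0301), with no filter (0.0192), without mobile control array 1 (0.0398) and without immobile control array 1 (0.0394), and not with an estimated correlation (0.377). Gadd45a, Cdkn1a, Plk2 (0.48 ± 0.07) and Bbc3 (0.51 ± 0.08) rose, the last on 1 of 3 probes. Mdm2, the main negative regulator of p53, differed by 0.39 ± 0.18 (adjusted p = 0.221), and Ccng1 by -0.23 ± 0.12 (adjusted p = 0.247). Of 27 ATF4 targets, 4 rose and 2 fell (7 and 2 adjusted over the list alone), among them the translation inhibitor Eif4ebp1 (1.14 ± 0.09) and Ddit3 (-0.70 ± 0.12). By camera this gave an adjusted p = 0.00651, and an adjusted p = 0.176 with an estimated correlation. Atf4 itself differed by -0.32 ± 0.41 (adjusted p = 0.687). Of 17 glucocorticoid-responsive genes, 5 rose and 1 fell (7 and 1 adjusted over the list alone). Camera gave these an adjusted p = 0.000803, and an adjusted p = 0.278 with an estimated correlation. Of 21 genes of the Nfe2l2 oxidative stress response, 7 rose and 1 fell (8 and 1 adjusted over the list alone). As a list they had an adjusted p = 0.00327 by camera and an adjusted p = 0.144 with an estimated correlation. The fallen member was Sod2, the mitochondrial superoxide dismutase (-0.42 ± 0.06). Of the metallothioneins, Mt1 rose (1.39 ± 0.14) and so did Mt2 (0.29 ± 0.06), the latter losing its call without mobile control array 3 (adjusted p = 0.0532). Ankrd1 differed by 1.65 ± 0.44 (adjusted p = 0.0511).

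Of 21 macrophage markers, 2 rose and 0 fell, Mrc1 (1.29 ± 0.21) and Ccl7 (1.45 ± 0.37), while 16 rose adjusted over the list alone. Ccl7 lost its call without mobile control array 2 (adjusted p = 0.135). The list had an adjusted p = 7.98e-07 by camera and an adjusted p = 0.377 with an estimated correlation. Its mean above the mobile controls was 1.89, 0.87 and 0.41 on immobile control arrays 1, 2 and 3. Of 24 interferon response genes, 5 rose and 0 fell (6 and 0 adjusted over the list alone), among them the chemokine Cxcl10 (1.26 ± 0.14). Together they reached an adjusted p = 6.45e-05 by camera and an adjusted p = 0.379 with an estimated correlation. Of 26 ribosomal protein genes, 11 rose and 0 fell (15 and 0 adjusted over the list alone), among them Rps19 (0.45 ± 0.06), on 1 of 2 probes (0.05 to 0.45). The list had an adjusted p = 2.36e-06 by camera and an adjusted p = 0.227 with an estimated correlation. Of 25 proliferation genes, 0 rose and 0 fell (0 and 0 adjusted over the list alone), while the list as a whole had an adjusted p = 0.000996 by camera and an adjusted p = 0.604 with an estimated correlation. That call was lost without immobile control array 1 (0.123) and with fry (0.245). Of 13 smooth muscle and pericyte markers, 0 rose and 2 fell (0 and 2 adjusted over the list alone), Rgs5 among them (-0.42 ± 0.05). By camera this gave an adjusted p = 0.0485, and an adjusted p = 0.410 with an estimated correlation. That call was also lost without mobile control array 3 (0.130), immobile control array 1 (0.0924) or immobile control array 2 (0.0730), and with fry (0.1004).

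The other lists did not pass for immobilization. Their adjusted p by camera was 0.0833 for insulin, IGF and myostatin signalling, 0.0939 for endothelium, 0.139 for erythroid cells, 0.140 for the clock, 0.151 for tendon, 0.325 for immediate early genes, 0.510 for adipocytes, 0.541 for neutrophils, 0.640 for heat shock, 0.659 for polyamines, 0.789 for extracellular matrix with fibroblasts and 0.814 for Schwann cells. Some of these were called in other settings. Insulin, IGF and myostatin signalling was called higher with fry (0.00840) and without both immobile arrays numbered 3 (0.0408). Endothelium was called lower without mobile control array 1 (0.0148), without immobile control array 3 (0.0447) and without both arrays numbered 3 (0.0251). Without mobile control array 1, tendon (0.0467) and erythroid cells (0.0398) were called lower, and without immobile control array 1 the clock was called higher (0.0281). Single genes of these lists did pass, among them the growth factor binding protein Igfbp5 (0.88 ± 0.08), Smad3, a mediator of myostatin signals (0.98 ± 0.16), the polyamine enzyme Odc1 (1.19 ± 0.18), the collagen cross-linking enzyme Lox (0.83 ± 0.13) and Tppp3 (-1.22 ± 0.13). Without mobile control array 1, 2 or 3, the risen genes numbered 337, 235 and 271, and without array 2 or 3 the fallen numbered 385 and 427. Of the 90 called genes that the rule for named genes took, 57 kept their call when each array was left out in turn.

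**Figure D2:**
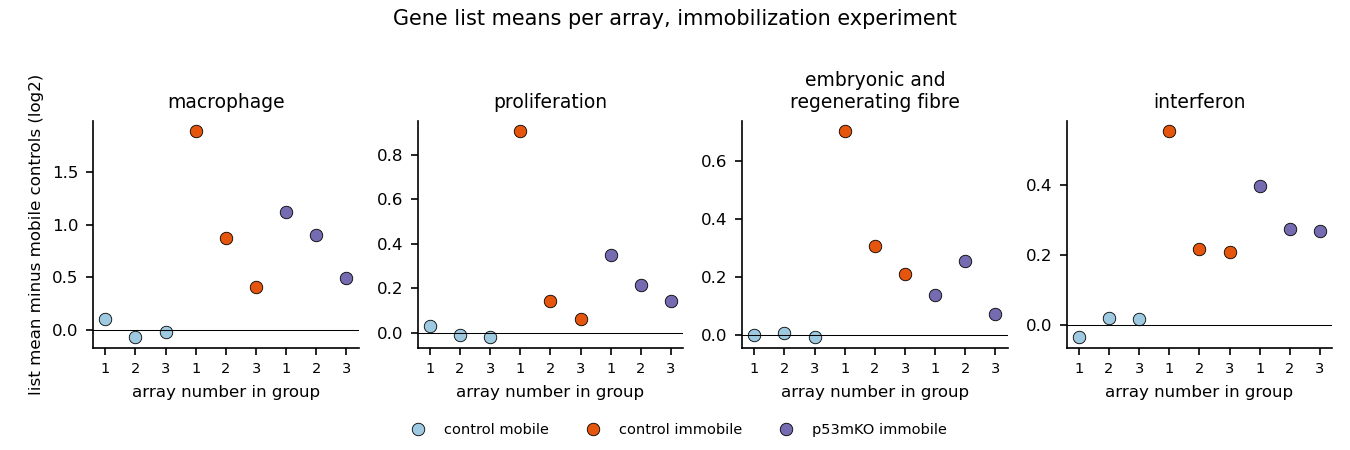
Mean log2 value of 4 gene lists on each of the 9 immobilization arrays, 1 point per array, relative to the mean of the mobile control arrays. The macrophage list lies at 1.89 and the proliferation list at 0.91 on immobile control array 1.

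Immobile limbs of p53 mKO mice were compared with immobile limbs of control mice to ask which of these responses differ in p53 mKO muscle. No gene passed the test of limma (0 risen and 0 fallen of 10842), and 319 genes had an unadjusted p under the threshold where chance gives 542.1. With the replicate number as a block, which pairs these arrays, limma also called 0 genes and 730 passed unadjusted, and over the other alternatives that number ran from 180 to 933 (933 with array weights). The main fit leaves this pairing out. Deviations shared by paired arrays widen its error, so a count below chance is no evidence that p53 loss has no effect. Except where the block is named, standard errors and p-values of genes and lists for p53 loss are unpaired. Fbxo32 was 14.02 ± 0.18 in p53 mKO and 14.01 ± 0.15 in control limbs, Trim63 12.74 ± 0.19 and 12.84 ± 0.18, and Gadd45a 13.30 ± 0.29 and 13.52 ± 0.54 (SD, n = 3). Cdkn1a, a direct target of p53, was 11.09 ± 0.21 in p53 mKO and 11.63 ± 0.32 in control limbs (log2 difference -0.55 ± 0.17 SE, limma's unadjusted p = 0.0126, adjusted p = 1). All 3 of its probes were lower in p53 mKO limbs, from -0.61 to -0.46, and 0 of them were called. None of 34 p53 targets passed (0 and 0 adjusted over the list alone), and the list did not stand apart from other genes (adjusted p = 0.289 by camera).

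By unadjusted p, the rule for named genes took Smarcb1, a chromatin remodelling subunit (-0.26 ± 0.04), Dusp11 (-0.19 ± 0.03), the Polycomb gene Suz12 (-0.22 ± 0.06), Ifngr1 (-0.23 ± 0.06) and the ubiquitin-like Nedd8 (-0.16 ± 0.04) on the lower side, and Mtres1 (0.23 ± 0.04), Myoz2 (0.27 ± 0.05), S100a13 (0.23 ± 0.04) and the mitochondrial genes Uqcrb (0.18 ± 0.03) and Fh1 (0.27 ± 0.05) on the higher side, none of which passed. Runx1 differed by -0.29 ± 0.08 and Chrna1 by -0.34 ± 0.12. Mdm2 differed by -0.08 ± 0.18, Ccng1 by 0.03 ± 0.12, Smox by 0.01 ± 0.23, Atf4 by -0.05 ± 0.41, Mt1 by -0.15 ± 0.14, Mt2 by -0.02 ± 0.06, Ankrd1 by -0.19 ± 0.44 and Myog by -0.52 ± 0.23, each with an adjusted p = 1. The probes of Chrna1, Myog, Mdm2, Gadd45a and Fbxo32 did not all have the same sign here.

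By camera, 7 lists stood apart from other genes although 0 of their members passed over all genes. They were mitochondrial respiration (higher, adjusted p = 0.000294), fast fibres (higher, adjusted p = 0.00285), embryonic and regenerating fibres (lower, adjusted p = 0.00104), denervation (lower, adjusted p = 0.00568), proliferation (lower, adjusted p = 0.0213), macrophages (lower, adjusted p = 0.0385) and neutrophils (lower, adjusted p = 0.0405). In the same order, these were adjusted p = 0.414, 0.753, 0.278, 0.278, 0.876, 0.876 and 0.876 with an estimated correlation, and 0 of the 7 passed with fry. The fast fibre call was lost with quantile normalization (0.623), the macrophage, neutrophil and proliferation calls with no filter (0.0554, 0.0553 and 0.0553), and the denervation call without both immobile arrays numbered 3 (0.0987). Adjusted over the list alone, 1 gene of mitochondrial respiration rose, and 0 genes of the other 6 lists changed. With the block, the clock list (higher, adjusted p = 0.0477) and the immediate early list (lower, adjusted p = 0.0188) were called as well. Without immobile control array 1, the macrophage list lay higher in p53 mKO limbs instead of lower (adjusted p = 0.00106), and so did proliferation (1.48e-11) and the interferon response (2.36e-06), while the embryonic (0.120) and neutrophil (0.205) calls were lost. Other single omissions ended calls too. Without immobile control array 2 the fast fibre (0.168) and neutrophil (0.313) calls were lost, and without immobile control array 3 the denervation call (0.0515). Without p53 mKO array 1 the fast fibre (0.0502) and neutrophil (0.0502) calls were lost, without p53 mKO array 3 those of denervation (0.0532), macrophages (0.997), neutrophils (0.606) and proliferation (0.599), and without mobile control array 1 that of neutrophils (0.0619). Single omissions also made calls. Without immobile control array 1, glycolysis was called higher (0.0251) and the glucocorticoid response lower (0.0191), and without immobile control array 2 the proteasome higher (0.00715) and immediate early genes lower (0.00715). Without immobile control array 3, the interferon response (0.0235) and ribosomal proteins (0.00345) were called lower and Schwann cells (0.00564) and the clock (0.0235) higher. Immediate early genes were called lower without mobile control array 2 (0.0395) or 3 (0.0332), Schwann cells higher without p53 mKO array 1 (0.0320) or both arrays numbered 3 (0.0285), and glycolysis higher without p53 mKO array 3 (0.0153).

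The fold changes of immobilization and of p53 loss correlated across genes at r = -0.428. Both use the immobile control arrays, and simulations with no effect and independent arrays and genes gave r = -0.733, with a covariance of -0.0128 against -0.0109 observed, a difference of 0.00190. Same-numbered immobile arrays deviated together, however. Simulations chosen after the data were seen, which keep those shared deviations and the correlation between genes, gave a mean r of -0.563 with 95% of values between -0.850 and -0.0934, and covariances between -0.0286 and -6.33e-05. With independent arrays these ranges were -0.980 to 0.279 and -0.0466 to 0.00135. The observed values lie inside all 4 ranges.

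Immobile p53 mKO limbs were also compared with mobile control limbs, to see which genes change in p53 mKO limbs under immobilization. No mobile p53 mKO limbs were measured, so genotype and immobilization both differ here. Gadd45a (2.31 ± 0.26), Fbxo32 (1.91 ± 0.17), Trim63 (1.41 ± 0.16), Chrna1 (1.44 ± 0.12) and Cdkn1a (0.97 ± 0.17) rose, and Perm1 (-2.04 ± 0.13), Smox (-2.24 ± 0.23) and Idh3a (-0.84 ± 0.08) fell, all chosen because they are named for immobilization above. In all, 485 genes rose and 572 fell, 34 and 44 of them at least 2-fold. Of 28 proteasome genes, 13 rose and 0 fell (22 and 0 adjusted over the list alone), and of 39 genes of mitochondrial respiration, 0 rose and 11 fell (0 and 13 adjusted over the list alone), with an adjusted p = 1.07e-11 and 1.33e-07 by camera and an adjusted p = 0.170 and 0.151 with an estimated correlation. Of the genes called here and in immobilized controls, 374 rose in both, 512 fell in both and 0 went opposite ways, against 24.7 and 36.4 expected of independent lists. The fold changes correlated at r = 0.946 across genes, against 0.231 in simulations with no effect and independent arrays, and the covariance was 0.0668 against 0.00282, a difference of 0.0640. With the correlation between genes kept, no effect gave r between -0.645 and 0.888 in 95% of simulations with independent arrays, which lies below the observed r. With the shared deviations kept as well it gave r between 0.411 and 0.971, which includes the observed r. The covariances lay between -0.00850 and 0.0161 and between 0.000906 and 0.0357, both below the observed one. Part of the overlap may come from the mobile control arrays that both comparisons share. The risen genes numbered 281, 157 and 209 without mobile control array 1, 2 or 3, 282, 268 and 293 without p53 mKO array 1, 2 or 3, and 874 without immobile control array 1, and the fallen numbered 290 and 335 without mobile control array 2 or 3 and 343 without p53 mKO array 2.

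Muscles transfected with a p53 plasmid were compared with muscles given a control plasmid to ask which genes respond to added p53. Genes of macrophages and of cell division were higher with the p53 plasmid and genes of energy metabolism were lower. Trem2, a receptor of macrophages, was 4.22-fold higher, at 12.91 ± 0.21 against 10.83 ± 0.17 (SD, n = 4), and Cdk1, the kinase of mitosis, was 3.01-fold higher, at 10.65 ± 0.23 against 9.06 ± 0.14. Fbxo32 and Trim63 were 2.84-fold and 2.80-fold lower, and Slc2a4, the insulin-responsive glucose transporter, was 2.69-fold lower. Of 10398 genes tested, 3144 rose and 2969 fell, 255 and 202 of them at least 2-fold. The smallest called log2 difference was 0.0525. With arrays centred on the median, 46.5% of called genes were risen, against 51.4% here. Called genes made up 58.8% of those tested, the share against which counts of list members stand.

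Among the largest rises were 6 histone H2A genes, H2ac10 (log2 difference 2.44 ± 0.20 SE), H2ac24, H2ac22, H2ac15, H2ac7 and H2ac12 (2.10 ± 0.16), near-identical copies that the probes may not tell apart. The others were Trem2 (2.08 ± 0.12), Chil3 (2.03 ± 0.13), Cd84 (1.86 ± 0.11), Clec4d (1.84 ± 0.16), Lat2 (1.84 ± 0.11) and Emp3 (1.83 ± 0.15). The largest falls were in Vmn1r65 (-2.24 ± 0.20), the glutathione-degrading enzyme Chac1 (-2.15 ± 0.36), Smtnl2 (-1.69 ± 0.20), Mt3 (-1.59 ± 0.19), Tpra1 (-1.57 ± 0.27), the aminotransferase Gpt2 (-1.57 ± 0.17), Fbxo32 (-1.50 ± 0.23, adjusted p = 0.000612) and Trim63 (-1.49 ± 0.28, adjusted p = 0.00176).

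Of 33 p53 targets, 13 rose and 13 fell (13 and 13 adjusted over the list alone), and the list did not stand apart (adjusted p = 0.863 by camera). Cdkn1a rose 2.03-fold (1.02 ± 0.18, adjusted p = 0.00143). Apaf1, an activator of caspases (0.68 ± 0.05), and Gtse1 (0.88 ± 0.07) rose by less. Ccng1 (-0.75 ± 0.09), the ribonucleotide reductase subunit Rrm2b (-0.60 ± 0.05) and Ddit4l (-1.22 ± 0.12) fell. Mdm2 differed by 0.16 ± 0.07 (adjusted p = 0.0671). Gadd45a fell (-1.21 ± 0.40, adjusted p = 0.0290), a call that was lost without p53 plasmid array 4 (adjusted p = 0.0699). Of 28 ATF4 targets, 7 rose and 11 fell (8 and 13 adjusted over the list alone), with an adjusted p = 0.747 by camera. The amino acid genes Phgdh (0.85 ± 0.07), Psat1 (1.19 ± 0.11), Asns (0.95 ± 0.12) and Slc7a5 (1.17 ± 0.10) were among the risen, and Atf4 itself fell (-0.16 ± 0.03) in this fit but not with all 17 arrays in 1 fit (adjusted p = 0.651).

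**Figure D3:**
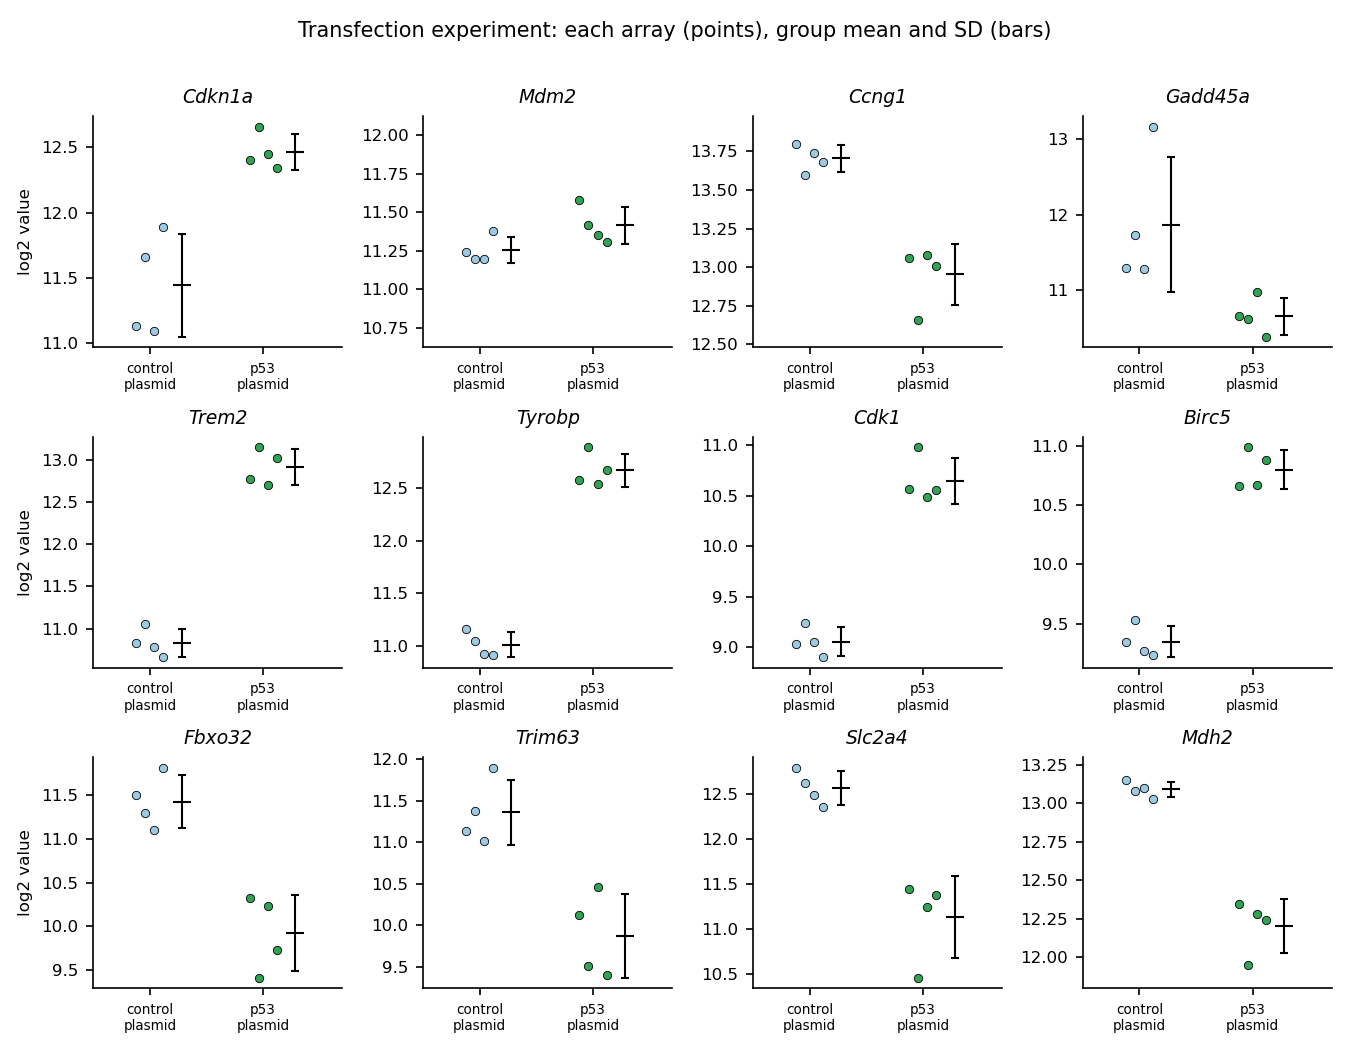
Log2 values of 12 genes on each of the 8 transfection arrays (points), with group means and SD (bars) for the control plasmid and the p53 plasmid. Cdkn1a lies at 12.46 ± 0.14 with the p53 plasmid and 11.44 ± 0.40 with the control plasmid, and Fbxo32 at 9.93 ± 0.43 and 11.43 ± 0.31.

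Of 22 macrophage markers, 21 rose and 0 fell (21 and 0 adjusted over the list alone), among them the signalling adaptors Tyrobp (1.66 ± 0.09) and Fcer1g (1.41 ± 0.08) and the macrophage marker Aif1 (1.39 ± 0.09). Camera gave these an adjusted p = 5.73e-09, and an adjusted p = 0.491 with an estimated correlation. Of 27 proliferation genes, 27 rose and 0 fell (27 and 0 adjusted over the list alone), among them Cdk1 (1.59 ± 0.12), Birc5, survivin (1.45 ± 0.09), and the replication helicase Mcm6 (1.23 ± 0.06). As a list they had an adjusted p = 2.39e-10 by camera and an adjusted p = 0.491 with an estimated correlation. Of 26 ribosomal protein genes, 21 rose and 1 fell (22 and 1 adjusted over the list alone), among them Rpl19 (0.67 ± 0.04) and Rps16 (0.55 ± 0.03). Together they reached an adjusted p = 2.14e-05 by camera and an adjusted p = 0.491 with an estimated correlation. Of 25 genes of extracellular matrix with fibroblasts, 12 rose and 1 fell (12 and 0 adjusted over the list alone), among them Timp1, an inhibitor of matrix proteases (1.46 ± 0.12), and the collagen gene Col1a2 (0.59 ± 0.11). The list had an adjusted p = 0.0383 by camera and an adjusted p = 0.698 with an estimated correlation. That call was lost without control plasmid array 3 (0.0584) or 4 (0.0558) and without p53 plasmid array 1 (0.0577), 2 (0.0629) or 4 (0.0645).

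Of 39 genes of mitochondrial respiration, 0 rose and 35 fell (0 and 35 adjusted over the list alone), among them the malate dehydrogenase Mdh2 (-0.89 ± 0.08), Ndufv2 (-0.51 ± 0.05) and Tfam, a factor of mitochondrial DNA transcription (-0.27 ± 0.03). By camera this gave an adjusted p = 6.36e-09, and an adjusted p = 0.491 with an estimated correlation. Of 22 genes of fatty acid oxidation, 2 rose and 18 fell (2 and 19 adjusted over the list alone), Cpt2 (-0.75 ± 0.06), Decr1 (-0.80 ± 0.08) and Acads (-0.53 ± 0.04) among the fallen and Angptl4 (1.38 ± 0.06) among the risen. Camera gave these an adjusted p = 0.000300, and an adjusted p = 0.611 with an estimated correlation. Of 16 glycolysis genes, 0 rose and 14 fell (0 and 14 adjusted over the list alone), among them Slc2a4 (-1.43 ± 0.21) and muscle glycogen phosphorylase Pygm (-1.20 ± 0.19). As a list they had an adjusted p = 0.00113 by camera and an adjusted p = 0.521 with an estimated correlation. Of 13 clock genes, 0 rose and 11 fell (0 and 11 adjusted over the list alone), among them the nuclear receptors Nr1d1 (-0.75 ± 0.06) and Nr1d2 (-0.81 ± 0.08) and Per2 (-0.62 ± 0.05). Together they reached an adjusted p = 0.000300 by camera and an adjusted p = 0.491 with an estimated correlation. Of 13 markers of smooth muscle with pericytes, 1 rose and 7 fell (1 and 8 adjusted over the list alone). Abcc9 was among the fallen (-1.38 ± 0.12, its 3 probes from -1.38 to -0.10), while the median of the list was -0.1225. The list had an adjusted p = 0.0366 by camera and an adjusted p = 0.491 with an estimated correlation.

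Several lists did not stand apart from other genes by camera with the preset correlation, though 4 of these 5 did in other settings. Of all genes tested, 58.8% were called with the p53 plasmid, so counts near that share do not set a list apart. Of 23 genes of atrophy, ubiquitin ligases and autophagy, 2 rose and 11 fell (3 and 12 adjusted over the list alone), with an adjusted p = 0.0659 by camera, the autophagy kinase Ulk1 (-0.60 ± 0.05) among the fallen. This list was called lower with fry (0.0127), with no filter (0.0271) and without control plasmid array 2 (0.0490) or 3 (0.0458) or p53 plasmid array 3 (0.0473). Of 28 proteasome genes, 3 rose and 12 fell (3 and 12 adjusted over the list alone), with an adjusted p = 0.0534. It was called lower with fry (0.0342), with no filter (0.0175) and without control plasmid array 1 (0.0337), 2 (0.0490) or 3 (0.0352) or p53 plasmid array 3 (0.0203). Of 17 fast fibre genes, 1 rose and 10 fell (1 and 10 adjusted over the list alone), with an adjusted p = 0.0699, among the fallen the calcium store protein Casq1 (-1.33 ± 0.16) and Actn3 (-0.60 ± 0.09). Fast fibres were called lower with quantile normalization (0.00626), with fry (0.00927), with no filter (0.0350) and without p53 plasmid array 2 (0.0331). Of 17 endothelial markers, 2 rose and 10 fell (2 and 10 adjusted over the list alone), with an adjusted p = 0.110, and were called lower with fry (0.0187) and with no filter (0.0495). Pecam1 (-0.35 ± 0.06) and Robo4 (-0.43 ± 0.04) fell, each on 1 of 2 probes, and Cd93, which macrophages also express, rose (1.14 ± 0.10). Of 26 interferon response genes, 10 rose and 4 fell (10 and 4 adjusted over the list alone), with an adjusted p = 0.318, Ifi27l2a rising (0.69 ± 0.05) and Igtp falling (-1.28 ± 0.22). The remaining lists had adjusted p by camera of 0.0549 for immediate early genes, 0.140 for adipocytes, 0.140 for the glucocorticoid response, 0.151 for lymphocytes, 0.176 for neutrophils, 0.179 for insulin, IGF and myostatin signalling, 0.339 for Schwann cells, 0.374 for tendon, 0.374 for denervation, 0.594 for the Nfe2l2 response, 0.714 for slow fibres, 0.863 for polyamines, 0.883 for embryonic and regenerating fibres and 0.905 for heat shock. Immediate early genes were called higher with fry (0.000960), with no filter (0.0234), without control plasmid array 2 (0.0316) and without p53 plasmid array 4 (0.0338). With fry, lymphocytes (0.00924) and neutrophils (0.0342) were also called higher, and adipocytes (0.000960), insulin, IGF and myostatin signalling (0.000960), the glucocorticoid response (0.0342) and tendon (0.0467) lower. Of single genes in these, Nqo1 (-0.97 ± 0.08), Deptor (-0.68 ± 0.07), Chrne (-0.43 ± 0.05), Runx1 (0.46 ± 0.11) and Smox (-0.85 ± 0.24) changed. Chrna1 rose by 0.72 ± 0.26 (adjusted p = 0.0404), and its call was lost without control plasmid array 1 (0.104). Myog (-0.11 ± 0.26), Ankrd1 (0.37 ± 0.31), Mt1 (0.21 ± 0.12) and Mt2 (-0.11 ± 0.08) did not pass. The size of a change differed between called probes, over 2-fold on the log2 scale, for Kcnc1 (-1.25 to -0.12), Abcc9 (-1.38 to -0.10), Mcm6 (0.20 to 1.23), Aif1 (0.27 to 1.39), Chrna1 (0.13 to 0.72), Nr1d2 (-0.81 to -0.17), Asns (0.23 to 0.95), Acads (-0.53 to -0.14), Actn3 (-1.54 to -0.60), Gtse1 (0.35 to 0.88), Apaf1 (0.29 to 0.68) and Deptor (-0.68 to -0.31). Of the 147 called genes that the rule for named genes took, 139 kept their call when each array was left out in turn.

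**Figure D4:**
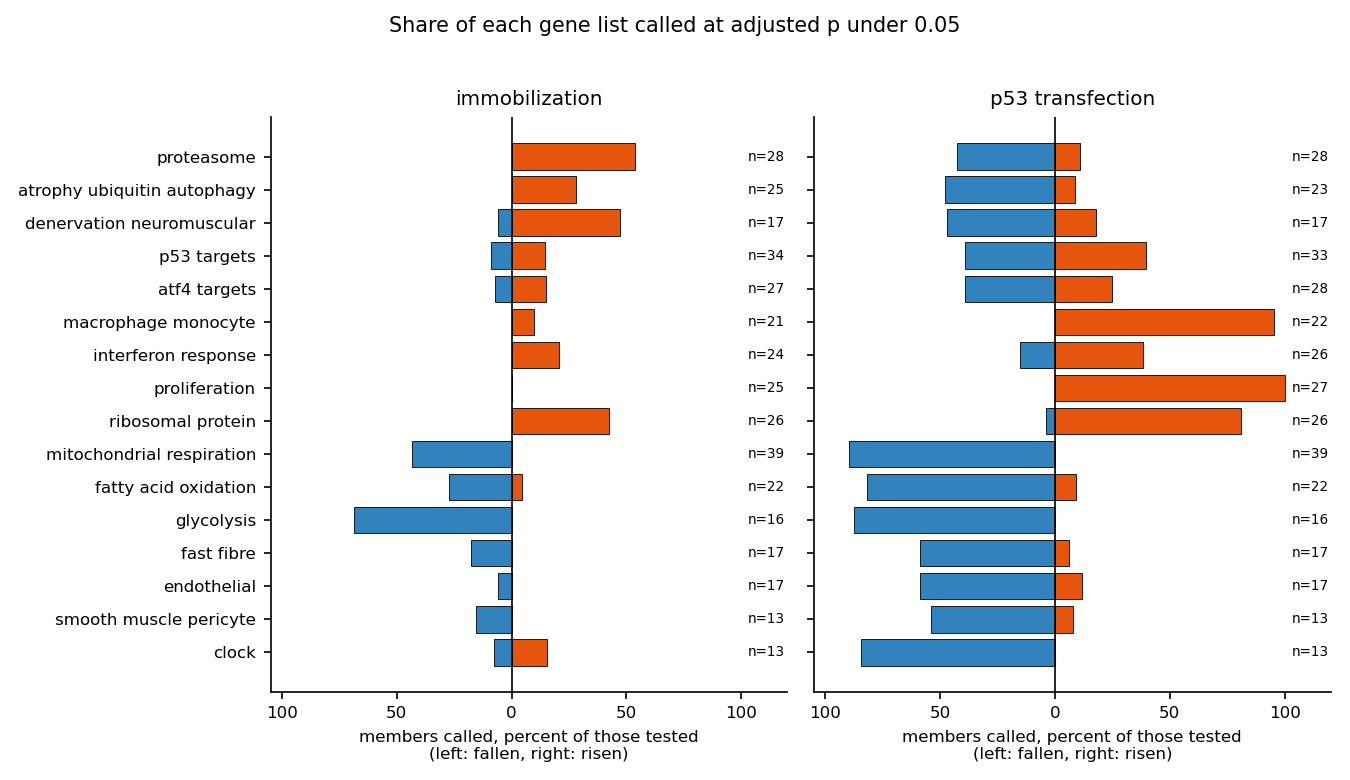
Percent of the tested members of 16 gene lists called risen (right) or fallen (left) for immobilization and for p53 transfection, with n the number of members tested. Proteasome genes rose in 15 of 28 cases with immobilization and in 3 of 28 with transfection, and genes of mitochondrial respiration fell in 17 of 39 and 35 of 39.

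The experiments were set side by side to ask whether added p53 changes the same genes as immobilization. Over 10059 genes tested in both, 325 rose in both and 556 fell in both, where independent lists of these sizes would share 161.6 and 202.8. Kcnc1 (-2.24 ± 0.08 with immobilization and -1.25 ± 0.17 with the p53 plasmid), Kcna7 (-1.62 ± 0.07 and -1.06 ± 0.15), Plpp7 (-1.21 ± 0.04 and -1.02 ± 0.08), Exd2 (-0.96 ± 0.05 and -0.69 ± 0.08) and Asb12 (-0.95 ± 0.11 and -0.85 ± 0.04) fell in both, and Nmt1 (0.84 ± 0.06 and 0.58 ± 0.04) and Cdkn1a (1.52 ± 0.17 and 1.02 ± 0.18) rose in both. Fbxo32, Trim63 and Gadd45a rose with immobilization and fell with the p53 plasmid, the last subject to the lost call given above. The test of the difference between the effects, added after the data were seen, gave -3.41 ± 0.31 for Fbxo32 (adjusted p = 4.38e-05), -2.99 ± 0.35 for Trim63 (adjusted p = 0.000124) and -3.73 ± 0.53 for Gadd45a (adjusted p = 0.000352). All 102 genes called in opposite directions passed this test. Genes chosen for opposite calls on these same arrays nearly must pass it, so it adds no support beyond those calls. The experiments differ in strain, intervention and perhaps batch, which these differences do not separate. In all, 83 genes rose with immobilization and fell with the plasmid and 19 went the other way, where 162.7 and 201.4 would be shared by independent lists.

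**Figure D5:**
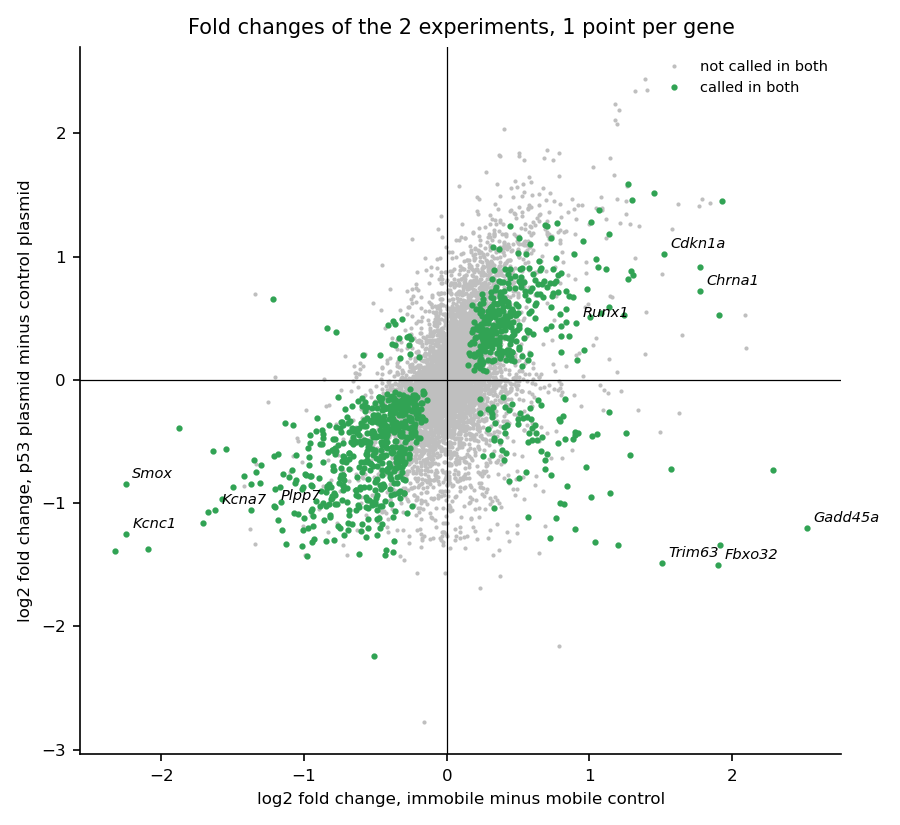
Log2 fold changes of genes tested in both experiments, 1 point per gene, with immobilization on the horizontal and p53 transfection on the vertical axis. Genes called in both are green, 325 risen in both, 556 fallen in both and 102 in opposite directions, Fbxo32, Trim63 and Gadd45a among the last.

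Across genes, which are not independent replicates, the fold changes of transfection and immobilization correlated at Pearson r = 0.520 (two-sided exact permutation p = 0.143) and Spearman rho = 0.513 (exact permutation p = 0.143). Those of transfection and p53 loss correlated at r = -0.527 (two-sided exact permutation p = 0.229) and rho = -0.465 (exact permutation p = 0.257). The Benjamini-Hochberg adjusted exact permutation p was 0.229 for both Pearson correlations, 2 having been computed, and 70 assignments allow a smallest p of 0.0286. Neither correlation passed, and other assignments of the plasmid labels reached 0.591 and 0.550. Without immobile control array 1, the correlation with p53 loss was 0.137 and that with immobilization 0.316. The shared counts also moved with single arrays. Risen in both numbered 184, 134 and 157 without mobile control array 1, 2 or 3, and fallen in both 336 without mobile control array 2. Opposite calls numbered 50 and 54 without mobile control array 2 or 3, and 204 and 66 without immobile control array 1 or 2.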

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

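The tests of the share of muscle fibre RNA, its dilution, a wrong label, regeneration and a processing batch were chosen only after the results they weigh were seen. Within groups of 4 arrays, a gap test asked whether 1 array lay far from the other 3, over 246 sets of values of named genes and gene lists. It singled out 17, and chance singles out about 1 in 20. No group of 3 was tested this way.

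With the control plasmid, array 4 lay apart for Lat2 (10.28, the others 10.69 to 10.76), Runx1 (9.40, the others 8.89 to 8.96), Deptor (10.43, the others 10.21 to 10.24) and the proteasome list mean (0.0965). Array 1 lay apart for Nr1d2 (11.07, the others 10.89 to 10.92).

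With the p53 plasmid, array 2 lay apart for Smtnl2 (9.66, the others 10.38 to 10.52), Ulk1 (9.21), Cpt2 (10.28), Decr1 (8.93), Cdk1 (10.98, the others 10.49 to 10.56) and Ccng1 (12.66), and for the list means of fast fibres (-0.459), mitochondrial respiration (-0.636), glycolysis (-0.821) and the clock (-0.602). In each of these, array 2 lay further from the control plasmid than the other 3 arrays. Array 4 lay apart for Junb (10.39) and array 1 for Runx1 (9.37). Without array 2, 2870 genes rose and 2765 fell.

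Probes with no gene listed also changed, in a part of the arrays that the comparisons of genes do not use. Of 939 tested, 86 were called for immobilization (37 risen, 49 fallen) and 65 for immobile p53 mKO against mobile control limbs (32 risen, 33 fallen). Of 910 tested for the p53 plasmid, 502 were called (286 risen, 216 fallen). For p53 loss limma called 0, with 35 under the unadjusted threshold.

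Macrophage markers rose and metabolic genes of the fibre fell with the p53 plasmid. A lower share of fibre RNA that raises every other cell type alike was argued against, since the median change of endothelial and smooth muscle markers was below 0, at -0.1425 over the p53 plasmid arrays, while the median of the macrophage markers was 1.20. Endothelial markers alone, without the smooth muscle list, had a median of -0.18, and lay between -0.2675 and -0.0575 on the p53 plasmid arrays. Medians of other cell types lay on both sides, at 0.369 for neutrophils, 0.245 for extracellular matrix with fibroblasts, 0.0675 for lymphocytes, -0.129 for adipocytes and -0.133 for Schwann cells, so that the types moved apart. A dilution of fibre RNA by 1 factor stays open. Metabolic genes fell beside contractile genes of matched level by a difference of -0.139, inside the spread of the control arrays, a weak test. Higher numbers of macrophages, or a change within them, and an effect of p53 in the fibres stay open as well, untested.

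Immobile control array 1 had higher macrophage (1.89 against 0.869 and 0.408) and proliferation means (0.907 against 0.144 and 0.0603) than the other 2. A transfected muscle under the wrong label was argued against by its interferon list mean of 0.554, where the transfected arrays had 1.96 to 2.33. Damage with regeneration in that limb is a candidate explanation, since its mean of the embryonic and regenerating fibre list was 0.703, above the other 5 immobile arrays (0.0737 to 0.306). The list was fixed before the data were examined, but the array was picked for its markers, so this remains a hypothesis. The list also shares Myog and Chrng with the denervation list, and its member Myh3 had no listed probe. Its mean therefore cannot tell regeneration from a stronger response of denervation genes on that array. A mixed sample was not tested.

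Immobile control and immobile p53 mKO arrays of the same number deviated together from their group means. A processing batch that follows the replicate number on all arrays was tested by the slope of mobile control deviations on those of the same-numbered p53 mKO array, whose mean was 0.0359. The slopes were 0.149, -0.0963 and 0.0549 for the mobile controls and 1.14, 0.583 and 0.986 for the immobile controls. The mobile slopes lie below, but by less than the range of the immobile slopes required, so that a batch of the immobile limbs alone, or of all arrays, stays open. Litter or the day of immobilization, which the labels do not give, may also lie behind it and were not tested.

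The results were compared with those of other splits of the same arrays into groups of the same size. For the p53 plasmid, 1 of 35 splits, the real one, called 6113 genes and the highest other called 0. That share is the smallest that 35 splits can give, so chance is unlikely but not excluded. Every other split mixes arrays of both plasmids, which widens the spread within its groups. The test also cannot tell p53 from a batch that follows the groups. Its 9 lists were not set apart from other splits, since 23 of 35 splits called as many and the highest other called 18. The split with 18 exchanges 1 array of each plasmid and so keeps part of the real contrast. This count therefore cannot decide whether the 9 lists arose by chance. For immobilization, 1 of 10 splits called as many as the real 1243 genes and the highest other called 0, and 3 of 10 called as many as 16 lists, the highest other also 16. For immobile p53 mKO against mobile control limbs, 1 of 10 called as many as 1057 genes and the highest other called 0. For p53 loss, 10 of 10 called as many as the real 0 genes, the highest other calling 1, and 5 of 10 called as many as 7 lists, the highest other also 7. With 10 splits no share under the threshold can be reached. In p53 loss, 319 genes passed an unadjusted threshold in the real split and up to 2159 in another that puts arrays 1 and 2 of the controls with array 1 of the p53 mKO, which points to a structure of the samples that follows the numbers. The real split parts all 3 same-numbered pairs and that split parts 1 of them. Among the 3 other splits that part all 3 pairs, 126, 152 and 160 genes passed the unadjusted threshold, fewer than in the real one, and 4, 7 and 7 lists were called.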

How the results depend on the processing

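The omission of both immobile arrays numbered 3, the covariate for macrophage markers and the count of opposite probes were chosen after the data were seen; the other alternatives were planned. For immobilization, the 553 risen and 690 fallen genes became 1060 and 1098 with all 17 arrays in 1 fit and 1449 and 1348 with array weights. The risen became 905 with an adjusted p under 0.1, which calls more by construction, and 970 with the macrophage covariate, with which 682 of the 1243 called genes remained and 63.7% of calls were risen, against 44.5%. Leaving out each array gave 235 to 679 risen (235 without mobile control array 2) and 385 to 729 fallen. For immobile p53 mKO against mobile control limbs (485 and 572), all 17 arrays gave 856 and 953, array weights 1138 and 1066, only the groups compared 919 risen and an adjusted p under 0.1 767 risen, and leaving out each array gave 157 to 874 risen and 290 to 685 fallen. Except for the threshold, and for fewer arrays, the cause was not tested. For the p53 plasmid, leaving out each array gave 2870 to 3054 risen and 2765 to 2848 fallen. Centring the arrays on the median called 6167 genes there, 46.5% of them risen against 51.4% in the main fit. Whether rises or falls are more numerous with the p53 plasmid thus depends on the normalization. For p53 loss, limma called 0 genes under each alternative run, with 180 to 933 at the unadjusted threshold.

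With the replicate number as a block, in a fit of the 2 groups compared, immobilization had 114 risen and 280 fallen genes, and 376 of the 1243 called genes remained. Same-numbered mobile and immobile control arrays correlated at 0.0848, 0.0696 and 0.181, so the data show no clear pairing and do not exclude one. The labels state none either, and the block uses up degrees of freedom. The block gave 3032 risen and 2830 fallen for the p53 plasmid, 537 and 501 for immobile p53 mKO against mobile control limbs, and 0 for p53 loss, where 730 genes passed unadjusted. Lists called with the block numbered 21, 9 and 12 for immobilization, p53 loss and the p53 plasmid. For immobilization it added p53 targets (higher, adjusted p = 0.0498), insulin, IGF and myostatin signalling (higher, 0.0350), slow fibres (lower, 0.0350), endothelium (lower, 0.0268) and tendon (lower, 0.0433), and for the p53 plasmid the proteasome (lower, 0.0421), atrophy (lower, 0.0456) and immediate early genes (higher, 0.0290).

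Lists called numbered 16, 7 and 9 for these 3 comparisons. With an estimated correlation they numbered 0, 0 and 0, with fry 17, 0 and 20, and with no filter 4 for p53 loss and 14 for the p53 plasmid; the cause was not tested. Leaving out each array gave 14 to 20, 4 to 10 and 8 to 12, the 4 without p53 mKO array 3. For p53 loss, 3 lists changed sign and were called higher without immobile control array 1, macrophages (adjusted p = 0.00106), the interferon response (2.36e-06) and proliferation (1.48e-11). The interferon response was called lower without immobile control array 3 (adjusted p = 0.0235). Over all omissions the signed adjusted p, negative for lower and not an order of strength, ran from -0.997 (without p53 mKO array 3) to 0.00106 for macrophages, from -0.727 to 0.822 for the interferon response, neither end a call, and from -0.599 to 1.48e-11 for proliferation; the cause was not tested.

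The correlation of the p53 plasmid with immobilization ran from 0.316 to 0.599 over single omissions, that with p53 loss from -0.611 to 0.137 (0.137 without immobile control array 1), and that of immobilization with p53 loss from -0.566 to -0.330. Genes risen in both experiments numbered 134 to 368, fallen in both 336 to 598 and opposite 50 to 204, the lowest each without mobile control array 2; the cause was not tested.

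Of the called genes that the rule took, 43 of 90 for immobilization and 127 of 147 for the p53 plasmid kept their call under all alternatives tried on single genes, and 39 and 3 lost it with the block. No gene of the rule changed sign while called under those alternatives. Single probes differ, however. For the p53 plasmid, 41 of 6113 called genes had another probe called with the opposite sign, among them Tpm3 (-0.37 to 1.27), Smtn (-0.60 to 0.06) and Mbp (-0.94 to 0.33), and for immobilization 0 of 1243 did, by limma on single probes, with 44 having an opposite probe at all, called or not. Signs changed while uncalled in 54 of 6377 values of genes and 45 of 1290 of lists. For immobilization, 51 values of genes lost and 35 gained a call over the alternatives other than single omissions, and 129 and 20 over these. For the p53 plasmid the numbers were 26 and 9, and 43 and 9. Signal near the floor limits what can be called among dim genes.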

Other observations

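The comparison of the interferon list between experiments was chosen after the values were seen. Relative to the mobile control limbs, its mean was 1.98 to 2.29 on the control plasmid arrays and 1.96 to 2.33 on the p53 plasmid arrays. The 2 experiments differ in intervention and strain, and any batch follows the experiment, so that no cause can be named. In the immobilization experiment the first principal component held 50.4% of the variance and the next 28.7%, on which the immobile arrays numbered 3 lay at -16.8 (control) and -15.8 (p53 mKO) and immobile control array 1 at 17.01, as far out on the other side.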
